A study of Homo sapiens with 4 samples.

How the data were processed

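The measurements are RNA sequencing of HepG2 cells, an established human hepatoma line, after silencing of METTL3. METTL3 is the catalytic subunit of the complex that places N6-methyladenosine on messenger RNA. Per the labels' protocols, cells received an siRNA against METTL3 or a scrambled control siRNA, were transfected again at 48 and 96 hours, and were collected on day 7. Poly(A) RNA was made into TruSeq libraries and sequenced on a Genome Analyzer IIx, per the labels' protocols. There were 2 groups of 2 libraries. The series design calls them biological replicates, and the labels do not say how the cultures were separated. The p-values of single features therefore measure the spread between these samples. The binomial and Fisher tests count listed features or genes, treat them as independent and measure no spread between samples.

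The authors deposited 4 tables, one each for genes, isoforms, exons and introns. The submitters' processing notes name CASAVA 1.8, TopHat 1.2.0, HTSeq, DESeq 1.5.24, Cuffdiff 1.0.3 and Cufflinks and the genome build hg18, without saying which program made which table. The tool behind the exon test is not given in the sources used here. Each deposited table lists only features with an adjusted p under 0.05 and a log2 fold change of at least 1 in either direction, as found from the values. Features outside the tables have no value here, so no test of enrichment could be made and no list could be adjusted over its own members.

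In the gene and intron tables the authors deposited a normalized signal, the mean read count of each group after division by a size factor, per the file headers. Their deposited fold ratio and log2 fold change compare the METTL3 knockdown mean with the control mean. The p-values in all 4 tables, raw and adjusted, are those of the authors' deposited tests. In the isoform table the authors deposited 1 FPKM value per group, per the file headers, with a natural log of the fold change that was converted to log2. These 3 tables hold group values without replicate values, so no SD and no new test could be given for them. The exon table holds a normalized read count for every library, which the authors deposited per the file headers.

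All exon values were whole multiples of 1 step per library, with a tolerance of 0.01 reads. A step, the worth of 1 read, was 1.26 and 0.958 normalized counts in the control libraries and 0.868 and 0.928 in the knockdown libraries. The steps rest on the listed exons alone, a selected part of each library with few low values, so the values were kept as normalized counts and tested on a log scale, and no count test was run. At these steps the median listed exon had 60 and 81 reads in the control libraries and 46.5 and 43 in the knockdown libraries. Library totals are unknown, since the tables hold only part of each library.

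The authors' log2 fold change of an exon is not the ratio of its group means. Over 438 exons with no group at 0, the median absolute difference was 0.357. For the 22 exons of single genes that are also in the gene table, it differed from the ratio by about the gene's own log2 fold change, with a median absolute remainder of 0.125 and 17 of 22 within 0.5. Across these 22 exons the difference and the gene's log2 fold change had a correlation of -0.37. The scale may be relative to the rest of the gene, which no source states.

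Genes, isoforms and introns were counted as the authors called them. Exons were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with Benjamini-Hochberg adjustment over the 474 listed exons and a threshold of 0.05. A fold change on this scale understates the change of low exons. The exons had been chosen by the authors from the same libraries, so the limma result is not independent evidence of a change. With 2 libraries against 2, an exact permutation test of a single exon cannot go below p = 0.333. On simulated data for the 474 exons with 200 changed, the limma step recovered 4.5% of exons changed 1.5-fold, 65.5% of those changed 2-fold and 95.5% of those changed 4-fold.

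Directions were compared with exact two-sided binomial and Fisher tests in SciPy 1.17.1, adjusted by Benjamini-Hochberg over 20 tests. Features of 1 gene are not independent, so each of these tests was also made with 1 feature per gene, the one with the smallest p. Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. A list with at least 5 listed genes was tested for direction against the other genes of the same table with a two-sided Fisher exact test, 33 tests in all, adjusted by Benjamini-Hochberg. On simulated gene lists of 10 members, of which 95% rose, the test at an unadjusted p of 0.05 found 99% of lists and called 3.4% of random ones. Of simulated lists of 10 members with the same share lower it found only 62.2%, since most listed genes are lower already, so falls are harder to call than rises. Pairs of tables were compared by gene symbol for the direction of shared genes, in a family of 6 tests. Each gene was represented by its feature with the smallest p, and merged loci were left out.

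Named genes were METTL3, every listed m6A writer, eraser or reader, and the 10 largest rises and 10 largest falls of the gene table. For these a normalized count of at least 20 in the higher group and a gene symbol were required, and genes with a group at 0 were left out. Up to 4 genes with the smallest adjusted p were named from each list with at least 3 listed genes. From the other tables came the 5 largest changes per direction, with at least 20 normalized counts or 1 FPKM in the higher group. Listed p53 pathway members were counted in these tables, and up to 6 per table were named. Some items that this rule selects are not reported here.

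Ensembl identifiers were matched to symbols in GENCODE 29, which gave a symbol for 1782 of 1977 genes, 417 of 471 identifiers in the exon table and 1818 of 2000 in the intron table. Of 4964 symbols in the isoform table, 4240 were current or had 1 current name in RefSeq for GRCh38.p14. Both references are of another genome build than the tables, so they served for names only and no coordinates are given. Exons and introns keep the numbers of the authors' tables. A locus that the authors merged from overlapping genes keeps the names of all its partners.

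The alternatives were an adjusted p of 0.01, a 2-fold minimum, a mean level of at least 50 normalized counts or 5 FPKM, recentring on the median log2 fold change of the listed features, and a pseudocount of 1 before the 2-fold minimum. For lists and overlaps they also included leaving METTL3 out and taking the largest fold per gene. For exons each library was left out in turn and the replicate number was used as a block. Count models and their filters, planned in case whole read counts were present, were not run.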

Results

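RNA was measured in 4 libraries of HepG2 hepatoma cells, 2 after METTL3 silencing and 2 after a scrambled control siRNA, on day 7 of treatment. The comparison asks which transcripts change in level or form when this RNA methyltransferase is depleted. The authors' deposited tables list 1977 genes, 7251 isoforms, 474 exons and 2672 introns as changed. Only the exon table holds values per library, so errors are given for exons alone.

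METTL3 itself fell in the knockdown. Its mean normalized count in the authors' deposited table was 955 in the control and 241 in the knockdown, a 3.96-fold fall (log2 fold change -1.99, authors' adjusted p = 1.71e-61). The listed METTL3 isoform fell from 35.6 to 7.47 FPKM in the authors' deposited table. The authors' exon table merges METTL3 with its neighbours RAB2B and TOX4, and 8 exons of this RAB2B+TOX4+METTL3 locus were listed, all lower. Exon 40 went from 265.7 ± 30.8 to 67.1 ± 9.53 normalized counts (SD, n = 2 per group), with a limma log2 fold change of -1.97 ± 0.19 (SE, limma adjusted p = 0.00131).

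METTL3 was the only listed member of the m6A writer list in the gene table, and the eraser and reader list had no listed gene there. In the isoform table, 1 isoform each of the writer list members RBM15, WTAP and METTL16, the last a separate methyltransferase, was higher, with WTAP going from 8.36 to 18.5 FPKM in the authors' deposited table. METTL16 went from 4.76 to 11.9 FPKM and RBM15 from 0.521 to 1.06 FPKM in the authors' deposited table. An isoform of the reader YTHDF1 rose from 2.21 to 5.53 FPKM, and isoforms of HNRNPA2B1 and FMR1 fell from 296 to 135 and from 3.95 to 1.15 FPKM, in the authors' deposited table. An isoform of the demethylase FTO was listed at 0 in the control and at 0.255 FPKM in the knockdown. Single introns of YTHDC2, HNRNPC, HNRNPA2B1 and IGF2BP3 were lower, by log2 fold changes of -1.30, -1.13, -1.03 and -1.59 in the authors' deposited table. Of these 4 falls, 3 are smaller than the median change of the listed introns, -1.36, and so change sign when recentred on it.

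Of the 1977 genes the authors called, 816 were higher and 1161 lower in the knockdown. Secretogranin SCG2, a granule protein of endocrine cells, rose from 25.2 to 1163 normalized counts in the authors' deposited table (adjusted p = 8.04e-181). UNC13A, a synaptic vesicle priming factor, rose from 8.72 to 577 normalized counts, and the adhesion molecule NECTIN4 from 2.81 to 157, in the authors' deposited table. The other large rises began near 0 in the control: the transcription factor TFEC reached 42.1 normalized counts, SLAMF7 27.6, cardiac troponin TNNT2 22.1 and the TNF receptor family member EDA2R 58.3 in the authors' deposited table. RPL21P65, SAA1 and UGT1A6, with log2 fold changes of 6.67, 5.98 and 5.58 in the authors' deposited table, have near-identical relatives and are uncertain.

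Among the falls, GBP2, an interferon-induced GTPase, went from 196 to 10.0 normalized counts and NEBL, a nebulin family gene, from 155 to 5.59 in the authors' deposited table. The transcription factor ST18 fell from 82.5 to 3.85 normalized counts, the lipoxygenase ALOX12B from 20.4 to 0.867 and the zinc finger gene ZNF90 from 39.6 to 1.73 in the authors' deposited table. KRT17P1, AKR1C4, PPIAP9, KLRC2 and KLRC3 had the 5 largest falls, with log2 fold changes of -7.66, -7.02, -6.88, -6.70 and -5.50 in the authors' deposited table, and share sequence with close relatives, so these are uncertain.

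Lower features outnumbered higher ones in every table. By the authors' fold changes they were 58.7% of genes, 53.3% of isoforms, 68.6% of exons and 71.7% of introns. The even split was rejected in each by an exact two-sided binomial test, with Benjamini-Hochberg adjusted p of 2.19e-14, 2.85e-08, 1.4e-15 and 2.4e-113. The share of lower features was greater among introns than among genes by 12.9 percentage points (Fisher's exact test, adjusted p = 1.8e-19), and by 11.5 points with 1 intron per gene (adjusted p = 1.92e-13). Exons and introns did not differ detectably (Fisher's exact test, adjusted p = 0.178). The authors' exon fold change is not the ratio of group means, so the exon share may not be on one scale with the others. Of 438 listed exons with no group at 0, 5 had the opposite sign to that ratio. Recentring on the median of the listed features, which lies at the edge of the lower features because no feature under 2-fold is listed, left 1022 genes, 4791 isoforms, 234 exons and 1140 introns. The splits then turned to 79.8%, 70.7%, 63.7% and 66.4% higher. Recentring shifts every feature of a table alike, so a change of sign marks only a fall smaller than that table's median change.

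**Figure D1:**
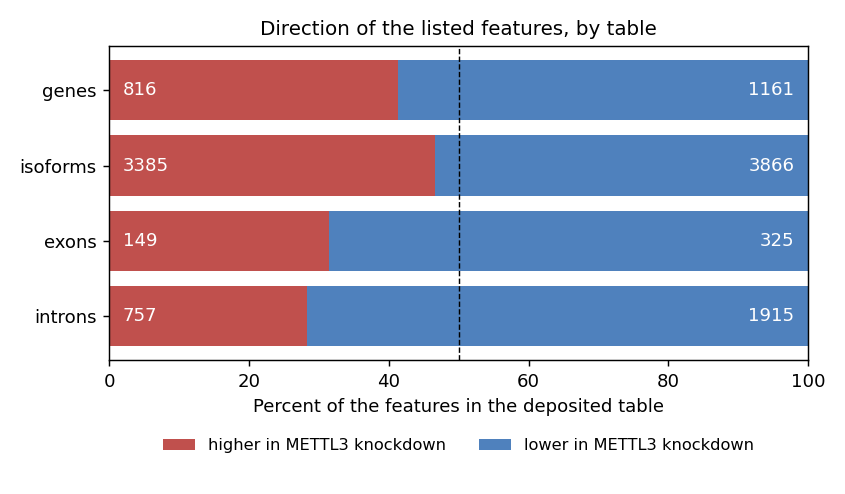
Percent of the features of each deposited table that were higher (red) or lower (blue) in METTL3 knockdown; the numbers in the bars are counts and the dashed line marks an even split. Directions are those of the authors' fold changes, which for exons are not the ratio of group means. Lower features were 58.7% of genes and 71.7% of introns.

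Inflammatory genes were higher where listed. All 8 listed members of the NF-kB and acute phase list were higher, against 41.0% of the other listed genes (two-sided Fisher's exact test, p = 0.000825, adjusted p = 0.0136). ICAM1, a leukocyte adhesion molecule, rose from 12.8 to 165 normalized counts and the neutrophil chemokine CXCL8 from 5.13 to 50.5 in the authors' deposited table. Complement C3 rose from 1911 to 4128 and the acute phase protein SAA1, whose reads its near-identical relative SAA2 can share, from 0.678 to 42.6 normalized counts in the authors' deposited table. Without SAA1 and SAA2, an alternative chosen after seeing the data, all 6 genes left, and all 8 in the isoform table, were higher but the list did not pass (Fisher's exact test, adjusted p = 0.0674 for genes and for isoforms). Isoforms of the same list were higher for 10 of 10 genes (Fisher's exact test, adjusted p = 0.0136). After recentring, where most remaining genes are higher, the list no longer stood apart (adjusted p = 0.673 for genes and 0.534 for isoforms by Fisher's exact test). All 8 genes, and all 10 in the isoform table, were still higher. This is the most extreme rise, so the recentred test could not have called one. With a mean of at least 50 normalized counts only 4 of the 8 genes were left, too few for the test.

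Beside these, the 3 listed markers of blood, endothelial or neural cells were also higher. Endothelial cadherin CDH5 went from 161 to 1143 normalized counts, the synaptic protein SYP from 27.0 to 69.2 and the monocyte receptor CD14 from 4.65 to 24.8 in the authors' deposited table.

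All 10 listed members of the interferon response list were lower in the authors' deposited table, but the list's direction did not pass adjustment (two-sided Fisher's exact test, p = 0.00694, adjusted p = 0.068). IFIT2, an inhibitor of viral translation, fell from 966 to 102 normalized counts, IFIT1 from 813 to 219, HERC5 from 375 to 127 and IFIT3 from 541 to 245 in the authors' deposited table. Of 15 genes of this list in the isoform table, 13 were lower (Fisher's exact test, adjusted p = 0.068), and in the intron table, with 5 genes, 3 were lower and 2 higher (Fisher's exact test, adjusted p = 0.850). After recentring 4 of the 10 genes stayed past 2-fold, and 3 of the 18 lower isoforms of the list changed sign.

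Of 8 listed immediate early genes, 7 were higher (two-sided Fisher's exact test, p = 0.0103, adjusted p = 0.068). At the authors' adjusted p of 0.01, all 6 that were left in the gene table were higher and the list passed there (Fisher's exact test, adjusted p = 0.0428). Of its 9 genes in the isoform table, 6 were higher and it did not pass (Fisher's exact test, adjusted p = 0.585, and 0.540 at the authors' adjusted p of 0.01). IER3 rose from 367 to 1046 normalized counts, FOSL1 from 31.2 to 224, the stress factor ATF3 from 309 to 949 and the MAP kinase phosphatase DUSP6 from 70.9 to 276 in the authors' deposited table. The lower member was EGR1, named after its values were seen, which went from 68.0 to 17.5.

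The p53 pathway list, 60 genes, had 22 members in the gene table, 15 higher and 7 lower (two-sided Fisher's exact test, p = 0.0148, adjusted p = 0.0814, not past the threshold). The members with the smallest p were CCNE2, a cyclin of the G1/S transition, which fell from 1465 to 205.0 normalized counts, and the ribonucleotide reductase subunit RRM2, which fell from 4961 to 2153 in the authors' deposited table. The damage kinase ATM fell from 6247 to 2889 and the cyclin-dependent kinase CDK6 rose from 6171 to 12748 normalized counts in the authors' deposited table. Of the 7 lower genes, 1 changes sign on recentring. The isoform table held 33 genes of the p53 list with 60 isoforms, 38 of them higher (Fisher's exact test per gene, adjusted p = 0.106). The cell cycle inhibitor CDKN1A rose from 40.1 to 142 FPKM, CCND1 from 13.5 to 31.1, RRM2B from 8.34 to 19.7 and SESN2 from 5.86 to 11.8 in the authors' deposited table. CDK6 and ATM isoforms moved as their genes did.

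All 5 listed cell cycle and mitosis genes were lower (two-sided Fisher's exact test, p = 0.0815, adjusted p = 0.224), 2 of which change sign on recentring. With 5 genes this is the most extreme fall, so the test could not have called one. Topoisomerase TOP2A fell from 24867 to 9456 normalized counts, the spindle protein NUSAP1 from 7697 to 2759, CDK1 from 4207 to 1971 and E2F2 from 556 to 223 in the authors' deposited table. In the unfolded protein and ATF4 list 7 of 9 genes were higher (Fisher's exact test, adjusted p = 0.123). The amino acid transporter subunits SLC7A5 and SLC3A2 rose from 16515 to 35761 and from 6940 to 15282 normalized counts in the authors' deposited table. The amino acid synthesis genes PHGDH and ASNS of the same list fell, from 3741 to 1337 and from 3208 to 1447, in the authors' deposited table.

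**Figure D2:**
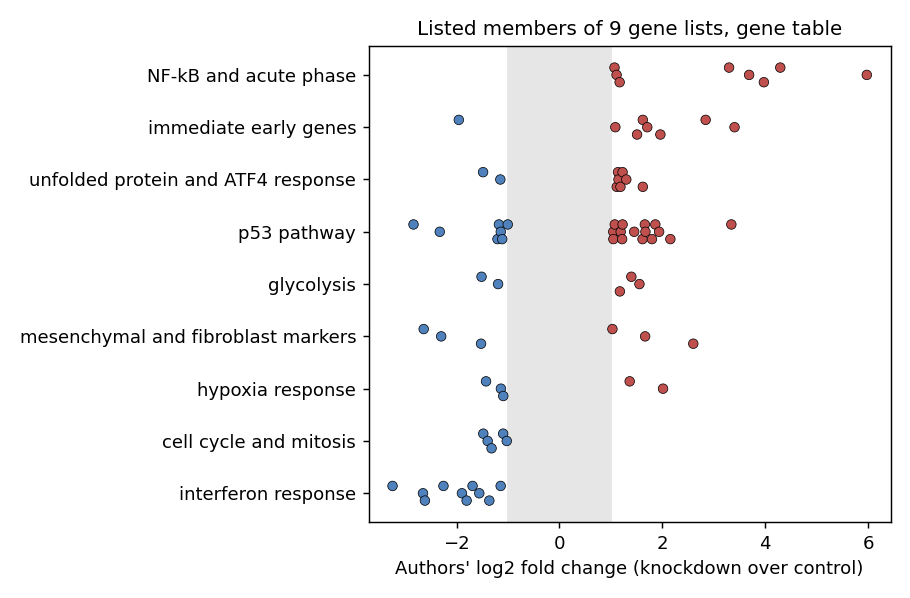
Authors' log2 fold change of each listed member of 9 gene lists in the gene table; each point is a gene, red if higher and blue if lower in METTL3 knockdown, and the grey band holds no listed gene. The 8 inflammatory genes lie to the right of the band and the 10 interferon genes to its left.

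Of the 33 tests of list direction over the gene, isoform and intron tables, 2 passed adjustment, both of the NF-kB and acute phase list with SAA1 and SAA2 included. The remaining lists tested in the gene table were mixed in direction. Of 5 glycolysis genes 3 were higher (two-sided Fisher's exact test, adjusted p = 0.643). The glucose transporters SLC2A1 and SLC2A3 rose from 1383 to 4066 and from 2019 to 4558 normalized counts, and hexokinase HK2 from 824 to 2171, while enolase ENO2 fell from 880 to 308, in the authors' deposited table. In the hypoxia list ADM and LOX rose 4.04-fold and 2.58-fold, and P4HA1 and CA9 fell 2.13-fold and 2.69-fold, in the authors' deposited table. Of the 3 lower hypoxia genes 1 changes sign on recentring. Among 6 mesenchymal genes 3 were higher: the matrix genes LUM, COL3A1 and DCN fell 4.92-fold, 2.88-fold and 6.23-fold, and the cadherin CDH2 rose 2.04-fold, in the authors' deposited table. No member of the SR protein, hnRNP, CLK kinase, core spliceosome, ribosomal protein, oxidative phosphorylation, mitochondrially encoded or nonsense-mediated decay lists was in the gene table.

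The 7251 isoforms belonged to 4959 genes, with 3385 higher and 3866 lower in the knockdown. Leaving out 296 isoforms named as small noncoding RNAs, 1310 genes had at least 2 listed isoforms, and 536 of these (40.9%) had isoforms going in both directions. When directions were shuffled over isoforms, 784 such genes were found on average, with a range of 735 to 836 over 1000 shuffles. The largest rises were isoforms of the nucleotide synthesis enzyme IMPDH1 (0.00487 to 6.24 and 0.0111 to 9.97 FPKM), PALM2AKAP2 (0.00277 to 2.81), the tumour suppressor MEN1 (0.00958 to 6.60) and RP11-159J16.1 (0.00848 to 2.66) in the authors' deposited table. The largest falls were isoforms of EPN2 (3.48 to 0.00319 FPKM), FOLH1 (2.36 to 0.00295), VIT (1.54 to 0.00213), RALGDS (1.75 to 0.0044) and SCMH1 (4.74 to 0.0397) in the authors' deposited table. Some of these genes had listed isoforms in both directions. Higher were 2 of 4 for IMPDH1 and for RALGDS, 3 of 5 for PALM2AKAP2 and for MEN1, and 2 of 7 for SCMH1. The values are of single isoforms and do not give the level of the gene. Among the 7251 isoforms, 1312 (18.1%) were listed at 0 in 1 group. The count of isoforms was 2044 with a mean of at least 5 FPKM and 3313 with a pseudocount of 1 before the 2-fold minimum.

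The 474 exons lay in 352 genes or merged loci, and 325 were lower by the authors' fold change. By the limma test 456 passed an adjusted p of 0.05, 145 higher and 311 lower. The count was 271 with a mean of at least 50 normalized counts and 297 after recentring. An exon of UBE2Q2, a ubiquitin-conjugating enzyme, rose from 1.59 ± 0.47 to 51.2 ± 2.41 normalized counts (SD, n = 2 per group, limma adjusted p = 0.000351). Exon 6 of the kinesin KIF16B went from 3.50 ± 3.18 to 55.2 ± 0.573 (SD, n = 2, limma adjusted p = 0.00323), and exon 8 of the MTUS1+PDGFRL locus from 4.46 ± 4.53 to 66.7 ± 13.3 (SD, n = 2, limma adjusted p = 0.00553). Exon 9 of the mitochondrial unfoldase CLPX was listed at 0 and 3.83 in the control libraries and at 36.5 and 44.5 in the knockdown libraries.

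Exons also fell in the merged loci ERAP1+CAST, CDC123+SEC61A2+NUDT5 and TADA3+TTLL3 with a partner without a symbol, where control exons at 66.6 and 143, at 91.8 and 107, and at 35.2 and 29.7 normalized counts reached 0 in 1 knockdown library each. Exon 6 of the keratin gene KRT17 held the same values as exon 5 of its pseudogene KRT17P1 in all 4 libraries, 71.7 and 362 in the control and 2.60 and 1.86 in the knockdown. Of the p53 pathway list, exon 30 of the INTS8+CCNE2 locus fell from 753 ± 114 to 117 ± 16.0 (SD, n = 2, limma adjusted p = 0.000894).

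**Figure D3:**
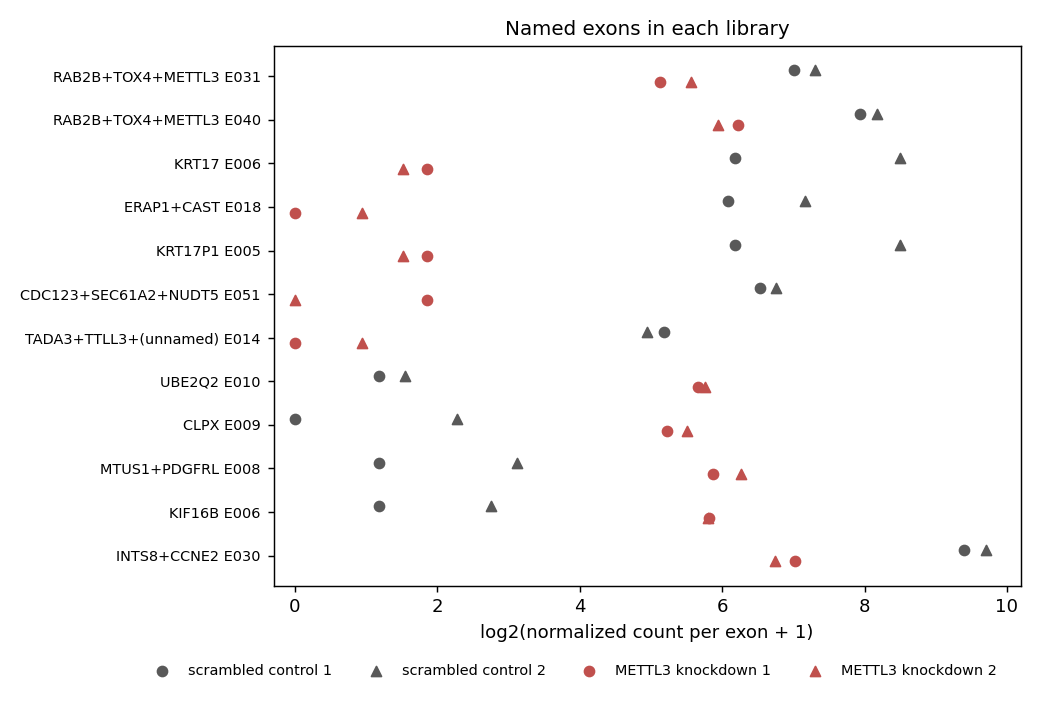
Normalized counts of named exons in each library, on a log2(value + 1) axis; grey marks the 2 scrambled control libraries, red the 2 METTL3 knockdown libraries, and circles and triangles are replicates 1 and 2. Control and knockdown libraries do not overlap in any exon drawn, nor in 469 of all 474 listed exons. The authors chose the listed exons as changed in these same libraries, so this separation is no independent evidence.

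Most introns were lower, 1915 of 2672 listed introns, in 1898 genes or loci. The largest falls in genes with a symbol were intron 7 of the zinc finger gene ZNF215, from 262 to 1.24 normalized counts, and introns 5 and 24 of the guanine exchange factor ARHGEF28, from 211 to 1.22 and from 53.6 to 0.42, in the authors' deposited table. Among the rises, an intron of LRRC9 went from 0.483 to 89.6 normalized counts, of the channel gene CNGB1 to 63.9, of MMP26 to 51.2 and of QRSL1 from 1.21 to 112 in the authors' deposited table. Of 448 genes with at least 2 listed introns, 418 (93.3%) had them all in 1 direction, against a mean of 243 and a highest value of 267 over 1000 shuffles of direction. The pregnancy zone protein gene PZP, chosen after its values were seen, had 26 listed introns, all lower.

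All 11 listed SR protein genes had only lower introns, 19 in all (two-sided Fisher's exact test per gene, p = 0.041, adjusted p = 0.123), 8 of which change sign on recentring. The 8 listed hnRNP genes had 12 introns, all lower (Fisher's exact test, p = 0.115, adjusted p = 0.253), 7 of which change sign on recentring. The falls were not limited to introns. In the isoform table all 6 listed SR protein genes were lower (Fisher's exact test, p = 0.0335, adjusted p = 0.123). Of 7 hnRNP genes there, 5 were lower and 2 higher (Fisher's exact test, adjusted p = 0.691). Of 4 listed core spliceosome genes, too few for the test, 2 were higher and 2 lower. Cell cycle genes had 18 listed introns in 8 genes, all lower (Fisher's exact test, p = 0.115, adjusted p = 0.253), with 5 changing sign. For 8 genes with introns only lower this is the most extreme fall, so the hnRNP and cell cycle intron tests could not have called one. Of the p53 list 12 genes had 16 listed introns, 12 lower. Per gene 8 were lower and 4 higher, no detectable departure from the other genes (Fisher's exact test, p = 0.761, adjusted p = 0.866). Introns of CCNG2, BID, CCNE2 and CASP9 fell 6.30-fold, 2.60-fold, 4.62-fold and 2.46-fold, and that of CDKN1A rose 5.05-fold, in the authors' deposited table.

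The tables shared many genes. Of 1781 genes with a symbol in the gene table, 1498 had a listed isoform. By the isoform of smallest p, 1483 of these (99.0%) went in the same direction, against 51.7% expected from independent directions. By the isoform of largest fold the share was 96.8%. Other listed isoforms of the same gene can go the other way. The gene and intron tables shared 396 genes, 95.5% in the same direction against 59.4% expected from independent directions (two-sided Fisher's exact test, adjusted p = 3.65e-72). Isoforms and introns shared 752 genes, 83.0% in the same direction (Fisher's exact test, adjusted p = 9.8e-62). The exon table shared 26 genes with the gene table, 61.5% in the same direction, which did not differ detectably from independent directions (Fisher's exact test, adjusted p = 0.407). Exons against isoforms (128 genes, 55.5%, adjusted p = 0.336) and exons against introns (76 genes, 63.2%, adjusted p = 0.119) gave no detectable relation by Fisher's exact test either. If the authors' exon fold change is relative to the rest of the gene, listed exons are chosen for departing from their gene, so these 3 exon comparisons say little about whether exons follow gene level. All comparisons used the same 4 libraries and are not independent of each other.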

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

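Of 227 recomputed values, 21 from alternatives chosen after seeing the data, 208 stayed on their side of the threshold or within 1.5 times the count. The 208 include values that could not change, such as those of the 2-fold minimum in the deposited tables, so the count says little about stability. Lists and overlaps were compared by threshold, and a list that passed in neither setting was not checked for direction. On recentring, the cell cycle list in the isoform table went from 3 higher and 9 lower to 4 higher and 1 lower. The DNA replication list there went from 2 higher and 6 lower to 4 higher and 1 lower. These are genes, each counted by its isoform of smallest p among those still past 2-fold, so falls that no longer reached 2-fold had dropped out. Of the 14 lower cell cycle isoforms 0 changed sign, and of the 8 lower replication isoforms 1 did, so the lists did not reverse. Recentring on the listed median left 1022 genes, 4791 isoforms, 234 exons of the deposited table, 297 exons by limma and 1140 introns. It turned the shares of higher features to 79.8%, 70.7%, 63.7% and 66.4%, and ended the call of the inflammatory list, with Fisher's exact adjusted p of 0.673 for genes and 0.534 for isoforms. Its own construction accounts for this, since tables without features under 2-fold have medians of -1.10, -1.06, -1.33 and -1.36, at the edge of the lower features. A mean level minimum left 2044 isoforms, 284 exons of the deposited table and 271 by limma; a pseudocount of 1 left 3313 isoforms; each keeps fewer low features. Without SAA1 and SAA2, genes that can share reads, the inflammatory list missed the threshold with fewer genes, at Fisher's exact adjusted p = 0.0674 for genes and for isoforms. Without merged loci 309 listed exons were left. At an authors' adjusted p of 0.01 the immediate early list passed in the gene table alone, with Fisher's exact adjusted p = 0.0428; the cause was not tested. The 2-fold minimum changes nothing in the deposited tables, which are already limited to such features, and leaving METTL3 out changed no list call.

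With 1 library left out, limma called 338 to 407 exons, with the lone library assumed to vary like the other group. With the replicate number as a block limma called 447 exons, against 456 without. Deviations of same-numbered libraries had a correlation of 0.001 over the listed exons. These exons were chosen for a difference between the groups, so this value cannot exclude a pairing of same-numbered libraries. The labels state none. Without replicate values no paired analysis was possible for genes, isoforms or introns. In 25 cases under the minimum level, recentring or the stricter p, a list fell below 5 genes and was not tested. Count models were not run. Unknown library totals leave the depth behind genes, isoforms and introns open.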

Other observations

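The exon tests of merged loci were set out before their results were seen; the shuffles of partner direction, the comparisons of listed isoforms with single genes, and the tests on inflammatory genes and introns were chosen after.

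Liver genes were few in the gene table, which cannot show whether an absent gene was unchanged or too low to call. Only AGT, of 27 secreted proteins of hepatocytes, was listed, at 3.78 normalized counts in the control and 61.8 in the knockdown in the authors' deposited table. The hepatic uptake transporters SLCO1B3 and SLCO1B1 fell from 1005 to 258 and from 34.4 to 13.8, and the nuclear receptor HNF4G from 67.2 to 11.3, in the authors' deposited table. IDI1, of the mevalonate pathway, fell from 8186 to 2581 and the phosphatidate phosphatase LPIN1 from 1794 to 812 normalized counts in the authors' deposited table. Of the epithelial list CDH1 rose from 6.88 to 31.5 and CLDN3 from 0.484 to 12.1, and the histone genes H2AC6 and H2AC11 fell 2.25-fold and 3.52-fold, in the authors' deposited table. The replication genes CDC6 and POLE fell from 5406 to 2663 and from 3183 to 1556, and both change sign on recentring. Of the apoptosis list BCL2L1 rose 2.50-fold and BMF fell 3.46-fold in the authors' deposited table. These genes were named after their values were seen. The rises of AGT, CDH1 and CLDN3 began from few counts in the control, 3.78, 6.88 and 0.484. The matrix genes LUM, COL3A1 and DCN stood there at 8006, 2531 and 673 normalized counts, and the uptake transporter SLCO1B3 at 1005, in the authors' deposited table. Listed genes alone cannot show how far the cells resembled hepatocytes, and this was not tested.

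In the gene table all 8 listed inflammatory genes were higher and all 10 listed interferon genes lower. The interferon list did not pass (Fisher's exact adjusted p = 0.068), and the inflammatory list missed the threshold without SAA1 and SAA2 (0.0674). The inflammatory call also ended on recentring (0.673), but all 8 genes were still higher there, so that test could not have called a rise. For most interferon genes the levels argue against few reads per gene as the cause, by criteria set after these values were seen. The median was 288 normalized counts in the higher group, and 7 genes had a mean of at least 50. An authors' adjusted p under 0.001 was found for 8, but all were listed for a low adjusted p. With a mean of at least 50, all 7 genes left were lower and the list did not pass (Fisher's exact test, p = 0.0483, adjusted p = 0.159). For the inflammatory genes a median of 75.3 and 5 of 8 with an authors' adjusted p under 0.001 count against few reads, but only 4 had a mean of at least 50, under the minimum of 5 set after these values were seen, so few reads are left open. An effect of the siRNA sequence that does not act through METTL3 cannot be told apart from METTL3 loss, because the labels name 1 siRNA treatment against METTL3. A METTL3-dependent response stays open as the biological alternative, untested.

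Exon calls in merged loci may in part follow the level of a partner gene. Of 93 merged loci with listed exons, 44.1% had a partner in the gene table, against 10.8% of 259 single genes (two-sided Fisher's exact test, p = 9.46e-11). Counted per partner gene the share was 21.2% (Fisher's exact test, p = 0.00211). In loci with 1 such partner, 52 of 76 exons (68.4%) went in its direction, against 57.9% when the partners' directions were shuffled over the 37 loci (permutation test, p = 0.265), so the direction of the exons adds no detectable support. For the 52 loci without a listed partner, 55.8% had a partner with a listed isoform, against 45.5% of the 231 single genes not in the gene table (Fisher's exact test, p = 0.219), but counted per partner gene the share was lower than in single genes, 30.2% (Fisher's exact test, p = 0.00753), and a level change and a change in exon use cannot be told apart, since unlisted genes have no value.

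Introns of 1 gene that move together may follow the level of the whole gene. Where such a gene was in the gene table, 168 of 170 (98.8%, Wilson 95% interval 95.8 to 99.7) moved in the direction of their introns. For the other 248 genes, 89 had a listed isoform, and by the isoform of smallest p 77.5% of these (67.8 to 85.0) went the same way. A level change and altered intron removal cannot be told apart there, because genes under the table's limits have no value. Examples, chosen after their values were seen, are MCTP2 with 7 introns higher and CD46 with 6 lower, neither listed as a gene.

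Of the 1312 isoforms listed at 0 in 1 group, 18.7% were small noncoding RNAs by name, against 0.859% of the others; the median FPKM of the other group was 0.468. In 8 pairs of listed exons, 16 in all, the values were identical in all 4 libraries under different genes.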
